A study of Mus musculus with 3 samples.

How the data were processed

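The series holds single-cell RNA profiles of mouse lung in 3 groups: PBS, repetitive bleomycin, and repetitive bleomycin with engineered MSCs, an abbreviation the labels do not spell out. Each group is 1 library. Per the labels, the lungs were perfused with PBS, minced, digested with the enzymes of a tumour dissociation kit for 25 min at 37 degrees, passed through a 40 micrometre strainer, checked for viability above 90%, and loaded at 1200 cells per microlitre on a Chromium X, with 2 to 3 mice pooled per group. Per the submitters' processing notes, reads were processed with Cell Ranger 7.1.0 and Scanpy 1.9.3 on the mm10 mouse genome. Whether reads in introns were counted is not stated. The deposited matrices hold raw counts: UMIs per gene and barcode, whole numbers for 32285 genes, with empty droplets still in them. An annotated object that the labels mention was not used here.

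Each sample has 2 such matrices. Of the 5000 barcodes with most UMIs, 97.5% were shared between both matrices of the PBS sample, 99.3% for bleomycin and 99.2% for MSC-treated lungs, so both were read as the same captured cells. The matrix with more UMIs was used (69257756, 38103436 and 40975489 UMIs in PBS, bleomycin and MSC-treated samples) and the other (36411232, 29557126 and 29674837) served as an alternative. They were not summed, since a molecule could be counted more than once.

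A barcode was kept as a cell with at least 500 UMIs, raised where needed to 5 times the median of barcodes ranked 45000 to 90000, at least 300 detected genes and at most 20% mitochondrial UMIs. In PBS, bleomycin and MSC-treated samples 11832, 9661 and 9163 barcodes reached 500 UMIs, 595, 28 and 62 of them failed on genes, and 81, 14 and 10 on mitochondrial UMIs. Scrublet in scanpy 1.11.5, with an expected doublet rate of 0.06 and seed 0, predicted 544, 472 and 488 doublets (4.88%, 4.91% and 5.37%), which were removed. The kept cells held 78.0%, 86.6% and 87.1% of all UMIs, with medians of 3405, 2998 and 3234 UMIs and 1648, 1509 and 1568 genes per cell, and 2.68%, 1.58% and 1.92% mitochondrial UMIs.

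Cells of the 3 libraries were clustered together without integration: counts per 10000, log transform, 2000 variable genes chosen with the library as batch key, 40 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (igraph 0.11.9, seed 0). Variable genes left out sex-linked and mitochondrial genes. Each cluster was named from 24 fixed marker sets when at least 3 markers of a set were detected in 10% of its cells. It stayed unnamed when its 10 leading genes held more markers of another class, when a second class scored over 0.5 of the best, or when its cells were shallow with no marker of their class among the leading genes. Clusters kept out of a class are given with their shares. A class entered a comparison with at least 50 cells in both libraries.

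Within a class, UMIs were summed over its cells and expressed as CPM, counts scaled to that sum, with a prior count of 0.5 in ratios. Intervals are exact at 95%: binomial for shares, conditional on the total of both libraries for ratios. They cover counting error only. No tests were run, because cells of 1 library are not replicates. A gene with no counts in a library was set at a floor of 3 counts summed over the class, giving a bound. In total 26 gene lists were fixed, 24 of which had a class to be measured in; the lists for surfactant genes and for the transitional epithelial state had none. A member counted as measured with at least 30 UMIs in the class over the 3 libraries. A list is given by the median log2 ratio of its measured members, with an interval from 200 Poisson draws, and by its rank among 10000 random lists matched on expression in 20 bins. Of 426 symbols in the lists and marker sets, 3 (Aldoa, Ccl21a and Mx1) did not match a single gene of the files and were left out, and 38 symbols in the files belong to 2 gene identifiers each. Gene positions come from GENCODE release 21 for mouse (GRCm38).

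Genes are named by a fixed rule. For each comparison and each of the fibroblast-like, blood endothelial-like, macrophage-like, monocyte-like and T-like classes, the 2 genes highest and the 2 lowest by the interval bound nearest to 0 were taken among genes with at least 100 UMIs and 50 CPM, if the ratio stayed at least 2-fold after ambient subtraction. Mitochondrial, ribosomal, unnamed, haemoglobin, immunoglobulin, T cell receptor and sex-linked genes were left out. From each list the most abundant members and those with the largest ratio are given, and Cd47, Sirpa, Spp1, Col1a1 and Acta2 in any case.

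To ask whether the treated library lay nearer to PBS, the bleomycin cells of a class were divided at random. Genes at least 2-fold different between a part of them and PBS were compared with the rest, since a shared reference would bias the answer. The outcome was set beside 100 draws in which a group of bleomycin cells stood in for the treated library, whose range holds the sampling of cells and not the difference between preparations. For Spp1-positive cells, each cell was thinned to 1000 UMIs and shallower cells were left out, and the share in T-like and B-like cells is given as background. Free RNA was estimated from barcodes with 10 to 100 UMIs. The levels of 4 surfactant and club cell genes in T-like and B-like cells put contamination at 1.87%, 1.87% and 1.21% of the UMIs of a cell.

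The alternatives were the other matrix, a minimum of 1000 UMIs, a limit of 10% mitochondrial UMIs, doublets kept, resolutions 0.5 and 2.0, each library clustered alone, ambient subtraction, median-of-ratios scaling, thinning to 1000 UMIs, no minimum above 1 UMI for list members, and thresholds of 1.5-fold and 3-fold. Median-of-ratios scaling moved all log2 ratios of a class for bleomycin over PBS by -0.33 in fibroblast-like, -0.23 in blood endothelial-like, -0.18 in T-like, -0.11 in NK-like, and 0.14 in interstitial macrophage-like cells and in all macrophage clusters together. For MSC-treated over bleomycin it moved them by 0.14 in T-like, 0.12 in B-like, 0.11 in NK-like and -0.11 in ciliated-like cells, and by under 0.1 in the other classes. The filters, markers, gene lists, naming rule and the alternatives above were chosen before the data were examined. The limits for leaving a cluster unnamed were set with the files in hand. Added afterwards were all macrophage clusters as a unit, shares among immune cells, PBS cells thinned to bleomycin depth (a factor of 0.321, which left 8999 of 10612 cells), alveolar macrophage-like cells counted with the mixed macrophage cluster, and blood endothelial-like cells counted with the cluster of sparse droplets that mixed endothelial and fibroblast genes. List medians inside single clusters, and the interstitial class without a share of other macrophage clusters, were added then too. That share was the median, over the alveolar identity genes, of the rise in the class over the difference between the other cluster and PBS.

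The procedure was checked on simulated data made from these counts. Intervals held the true ratio for 95.2% and 95.6% of genes in alveolar macrophage-like cells (10193 genes for bleomycin over PBS and 10490 for MSC-treated over bleomycin) and for 96.5% of 5842 genes in fibroblast-like cells. A 2-fold change put the interval on the right side of 1 for 100% of changed genes in the alveolar class and 58% in the fibroblast class, where a 4-fold change did so for 82%. Lists planted with a 2-fold change came back at 1.02, 1.00 and 0.98. Other tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.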

Results

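Lungs of mice given PBS, of mice given repeated bleomycin, and of mice given repeated bleomycin and engineered MSCs were each profiled as 1 library of single cells from 2 to 3 pooled mice. Bleomycin breaks DNA in the cells lining the airspaces and is widely used to bring on scarring of the mouse lung. The design asks what repeated bleomycin changed in the cells of the lung, and how lungs of mice that also received the MSCs differed from those given bleomycin alone. With 1 library per group there was no spread between animals to measure, so no difference below carries a test, and the 95% intervals in brackets cover counting error only. After filtering, 10612 cells of the PBS library, 9147 of the bleomycin library and 8603 of the MSC-treated library remained. They were sorted into classes by marker genes, and each class is called "like" the cell type whose markers it carried.

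The PBS library stood apart from both bleomycin libraries in ways that ran through all its cell classes. More UMIs were counted per PBS cell, and larger parts of them came from genes that cells switch on when tissue is handled and from the mitochondrial genome. Free RNA in PBS also held more transcripts of red blood cells. Erythroid markers gave 1.38% of the UMIs in the barcodes used to estimate it, against 0.0325% in bleomycin and 0.111% in MSC-treated lungs. The RNA content of a cell was not separated from how deeply its library was sequenced. Any contrast with PBS within a class therefore contains this difference, whereas the MSC-treated and bleomycin libraries were closer to each other. Transcripts (UMIs) per cell were higher in PBS than in bleomycin in 10 of 10 classes, from 1.14-fold in interstitial macrophage-like to 3.67-fold in T-like cells, as the plot of UMIs per cell shows. Between the MSC-treated and bleomycin libraries the same ratio ran from 0.957 to 1.20. The 17 genes of the dissociation stress list had a median log2 ratio under 0 in 18 of 18 class comparisons with PBS, from -0.46 in fibroblast-like cells (-0.19 with its undetected member at its bound) to -1.57 in interstitial macrophage-like cells, both for bleomycin over PBS. Fos and Jun, which pair up as the early-response transcription factor AP-1, had log2 ratios of -2.27 and -2.12 in T-like cells, -1.13 and -1.07 in neutrophil-like cells, and -0.97 and -2.22 in alveolar macrophage-like cells. Junb, another AP-1 member, stood at -1.18 in T-like cells. Genes encoded by the mitochondrial genome, which specify parts of the respiratory chain, had medians from -0.68 in interstitial macrophage-like to -1.88 in neutrophil-like cells. Between the MSC-treated and bleomycin libraries the mitochondrial list was slightly higher in the treated library, from 0.16 in alveolar macrophage-like to 0.49 in conventional dendritic-like cells, except in neutrophil-like cells at -0.10.

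**Figure D1:**
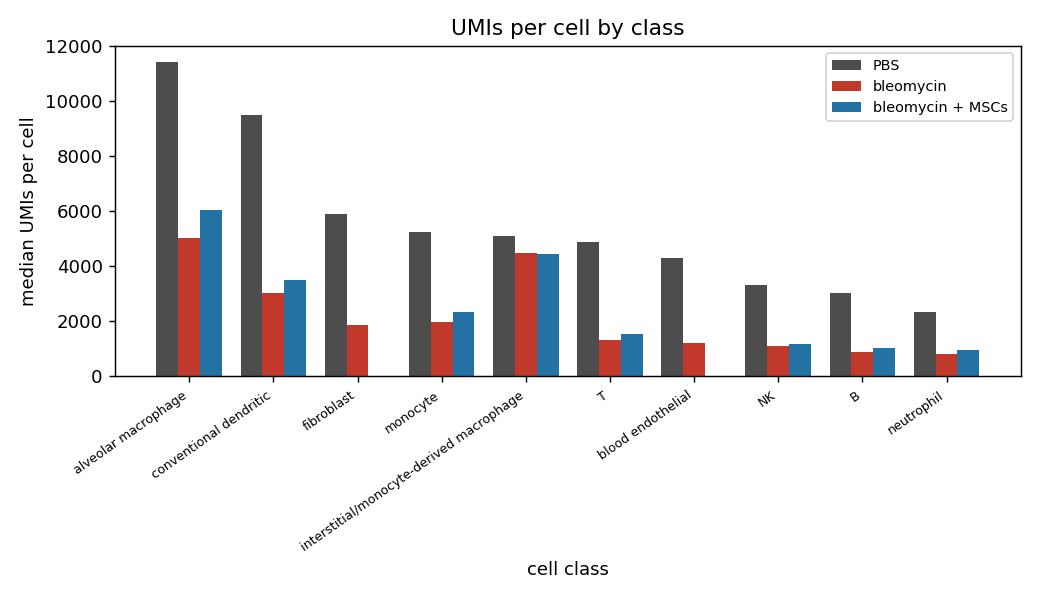
Median UMIs per cell (vertical axis) in each cell class (horizontal axis) for the PBS, bleomycin and MSC-treated libraries, 1 library per group; bars are left out for a class with under 50 cells in a library. PBS bars are the tallest in every class, with alveolar macrophage-like cells at 11431.5 UMIs in PBS against 5028.5 in bleomycin.

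Repeated bleomycin shifted the recovered lung from a mixture of B cells, vessel cells and resident macrophages to a suspension in which macrophages were the most numerous class. Macrophage-like cells as a whole gained ground, most of all a cluster that held few PBS cells, while a small sub-cluster held fewer cells in bleomycin than in PBS. Clusters are drawn on expression, so a cell whose genes changed could move between them. Blood endothelial-like, fibroblast-like and mural-like cells all made up a much smaller share. All macrophage clusters together held 11.03% of PBS cells and 50.1% of bleomycin cells, 4.54 times the share [4.26 to 4.85]. Alveolar macrophage-like cells, named for the resident phagocytes of the airspace, went from 9.54% to 33.0% [fold 3.23 to 3.72]. That rise lay mostly outside the cluster that held most of them in PBS, which had 846 cells in PBS and 852 in bleomycin. Interstitial or monocyte-derived macrophage-like cells, which lie in the tissue between airspaces, went from 1.44% to 4.56% [fold 2.62 to 3.83]. A further macrophage cluster scored highest for alveolar markers (1.155, against 0.544 for interstitial ones). Its 10 leading genes held 1 interstitial marker, Gpnmb, and no alveolar one, so it was kept out of both classes. This mixed macrophage cluster held 0.0471% of PBS cells (5 cells) and 12.5% of bleomycin cells (1141 cells). Finer clustering divided the interstitial class into a sub-cluster led by Pf4, with 128 cells in PBS and 35 in bleomycin, and another led by C1qa and Apoe, with 10 and 320. Counted as a share of immune cells alone the rise was smaller, 3.01-fold for all macrophages and 2.29-fold for alveolar macrophage-like cells, and other settings put the interstitial rise between 2.09-fold and 5.66-fold.

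The alveolar macrophage-like class was also made of different clusters in the libraries. A single cluster held 846 of the 1012 alveolar macrophage-like cells of PBS (83.6%) but 28.2% of those in bleomycin and 18.8% of those in the MSC-treated library. Another held 9.29%, 54.4% and 66.7% in the same order. In B-like cells a cluster with 91.4% of the PBS cells held 9.44% of the bleomycin cells, and a cluster of cells with few UMIs held 2.96% and 85.6%. Neutrophil-like cells divided likewise, with 93.7% and 1.55% in a cluster of richer cells against 6.34% and 98.4% in a cluster of sparser ones. Conventional dendritic-like cells leaned to a cluster of mature, migratory cells, at 19.3% in PBS and 53.4% in bleomycin. In T-like cells the main cluster went from 64.2% to 44.8%, and a cluster led by Cxcr6 and Icos from 16.4% to 33.8%, with 18.1% in the MSC-treated library. The main cluster of blood endothelial-like cells held 62.9% in PBS and 77.2% in bleomycin.

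Blood endothelial-like cells, which line the vessels, made up 16.7% of PBS cells (1774) and 3.84% of bleomycin cells (351), a share 0.230 times as large [0.204 to 0.258]. Fibroblast-like cells, which make the connective tissue matrix, went from 3.90% to 0.645% [0.124 to 0.218 times], and other settings put that ratio between 0.162 and 0.299. Mural-like cells, the contractile cells wrapped around vessels, numbered 190 in PBS and 5 in bleomycin, and lymphatic endothelial-like cells 25 and 8. A further 12.97% of PBS cells (1376), against 0.230% of bleomycin cells (21), sat in a cluster of sparse droplets that mixed endothelial and fibroblast genes, with a median of 788 UMIs and 6.27% mitochondrial UMIs. It was kept out of every class, and counting it with the blood endothelial-like cells would take their ratio from 0.230 to 0.137. Smaller clusters also stayed without a class: 1 led by satellite-repeat transcripts (0.942% of PBS cells and 0.0984% of bleomycin cells), 1 led by the inflammatory genes Cxcl2, Acod1 and Ccl3 (0.104% and 0.787%), 1 that mixed surfactant and airway secretory genes (0.528% and 0.536%), and a pair of mixed-cell clusters present in PBS (0.207% and 0.151%) and absent from bleomycin. With the libraries clustered together, no cluster could be named for alveolar type 1 or type 2 cells (PBS clustered alone held 38 alveolar type 2-like cells), so surfactant genes such as Sftpc and stress keratins such as Krt8 were not compared within an epithelial class.

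Among other immune cells, B-like cells went from 23.9% to 13.8% [0.539 to 0.618 times] and NK-like cells, innate killer lymphocytes, from 3.94% to 2.10%. T-like cells rose from 8.29% to 12.7% of all cells [1.40 to 1.68 times], but as a share of immune cells they stood at 13.5% and 13.7%. Neutrophil-like cells were at 6.83% and 6.33%, and with a minimum of 1000 UMIs per cell their ratio of 0.927 became 0.218, since the sparse bleomycin neutrophils fell under it, and that of B-like cells 0.228. Monocyte-like cells were at 5.14% and 3.84%. Counted among immune cells alone, the ratios were 0.382 for B-like, 0.353 for NK-like, 0.613 for neutrophil-like and 0.495 for monocyte-like cells. Conventional dendritic-like cells, which carry antigen to T cells, went from 1.76% to 3.05% (1.73 times, but 1.14 among immune cells), and plasmacytoid dendritic-like cells, producers of interferon, from 0.283% to 0.689%. Ciliated-like cells, which sweep the airway, were at 0.368% and 0.732%, mesothelial-like cells, the outer covering of the lung, at 5 and 32 cells, erythroid-like cells at 78 and 2, and basophil or mast-like cells at 17 and 4. Erythroid markers were also scarcer in the free RNA of bleomycin lungs than in that of PBS. Whether the preparations held different amounts of blood, and whether this affected the shares of immune cells found in blood, was not tested.

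**Figure D2:**
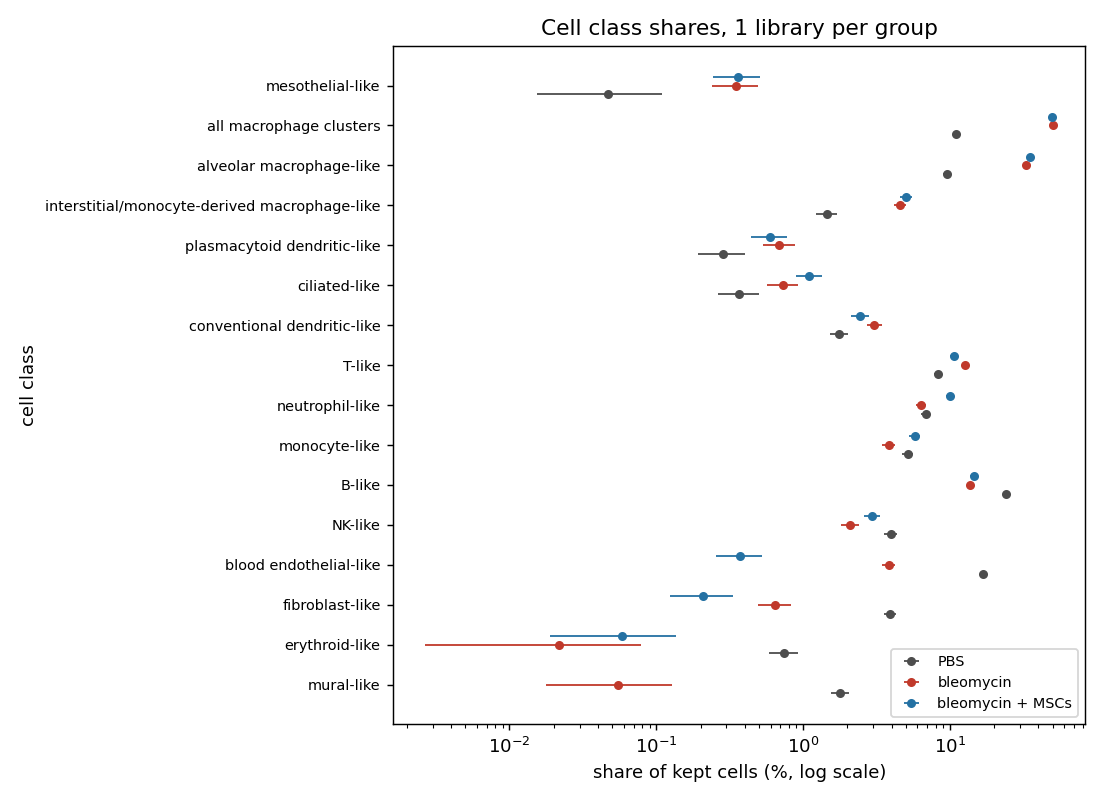
Share of kept cells (horizontal axis, percent, log scale) in each cell class (vertical axis), with exact 95% counting intervals, for the PBS, bleomycin and MSC-treated libraries, 1 library per group. Macrophage-like classes sit to the right in both bleomycin libraries and blood endothelial-like, fibroblast-like and mural-like cells to the left; the mural-like class has no point for the MSC-treated library because it held 0 cells.

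Macrophages of bleomycin lungs carried more transcripts of genes tied to scarring and fewer for showing antigen. Spp1 had the steepest rise of the profibrotic genes detected in both libraries in interstitial macrophage-like cells, where it was rare in PBS. Over whole classes the profibrotic shift was larger in interstitial macrophage-like cells than in alveolar ones, and it was smaller inside the finer sub-clusters of the interstitial class. Trem2 and Gpnmb are in the profibrotic list and also among the markers that name the interstitial class. Gpnmb among its leading genes kept the mixed macrophage cluster out of the alveolar class. The contrast between the classes is therefore partly set by how cells were sorted. The 15 genes of the profibrotic macrophage list had a median log2 ratio of 1.70 in all macrophage clusters together [1.67 to 1.74], with 14 of 15 members higher, 1.07 in alveolar macrophage-like cells [0.97 to 1.11] and 2.96 in interstitial macrophage-like cells [2.82 to 3.43]. Each of these medians lay above all of 10000 random lists of genes with like expression. In alveolar macrophage-like cells the median depended on which clusters were counted, falling to 0.75 with at least 1000 UMIs per cell and reaching 1.75 with coarser clustering and 2.15 with the mixed macrophage cluster included. Inside single clusters it was 0.57, 0.85 and 1.53 in the alveolar class, and 0.39 and 1.32 in the Pf4-led and C1qa-led interstitial sub-clusters.

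Spp1 (chromosome 5, 104435118 to 104441050, ENSMUSG00000029304) encodes osteopontin, a secreted matrix protein that draws in and activates cells. Its level in interstitial macrophage-like cells went from 21.4 to 8806 CPM, 399.7-fold [259.9 to 693], and in alveolar macrophage-like cells from 238.6 to 5976, 25.0-fold [24.1 to 26.0]. The alveolar value depends on the make-up of the class. Inside the cluster that held most of its PBS cells Spp1 went from 229 to 1122 CPM, and inside the one that held most of its bleomycin cells from 398 to 8755. With every cell thinned to 1000 UMIs, Spp1 was seen in 18.2% of alveolar macrophage-like cells of PBS and 71.6% of those of bleomycin, in 1.67% and 67.3% of interstitial macrophage-like cells, and in 16.3% and 76.7% of all macrophages. Unthinned shares were 65.8% and 90.2%, 5.23% and 78.9%, and 57.7% and 91.1%. The thinning left out 47 and 42 alveolar, 33 and 10 interstitial, and 80 and 75 of all macrophage-like cells. T-like and B-like cells, taken as the background, showed it in 0.115% and 8.66%, and in 0.278% and 10.4%. Their unthinned shares were 1.59% and 12.9%, and 0.987% and 10.8%, at median depths of 4876 and 1330 UMIs in T-like and 3028.5 and 895 in B-like cells.

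Other members of the profibrotic list followed Spp1 in interstitial macrophage-like cells. Gpnmb (chromosome 6, 49036546 to 49070929, ENSMUSG00000029816), a membrane glycoprotein of lipid-laden macrophages, was 79.8-fold higher [49.2 to 151]. Fabp5, a fatty acid carrier, was 60.1-fold higher, Mmp12, an elastin-cutting protease, 51.5-fold, and Ctsd, a lysosomal protease, 10.99-fold. Cd9, a membrane organizer, rose 5.42-fold, Lgals3, a galactose-binding lectin, 4.25-fold, and Trem2, a lipid-sensing receptor, 3.23-fold. Arg1, which consumes arginine in tissue repair, had no counts in PBS and was at least 23.2-fold higher, taking a floor of 3 counts for the class. Apoe, a lipid carrier, was the list's most abundant member there and its log2 ratio was -0.02. Mfge8, which tethers dying cells to phagocytes, was 92.9-fold higher [63.2 to 149.9].

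In alveolar macrophage-like cells Msr1, a scavenger receptor for modified lipoproteins, was 43.5-fold higher [29.5 to 70.3], Arg1 60.6-fold [20.7 to 628] from 2 counts in PBS, Mmp12 6.30-fold, Trem2 4.89-fold and Cd63, a lysosome and vesicle protein, 3.57-fold. Cd9, Ctsd and Lpl, the last an enzyme that frees fatty acids, rose 1.21-fold, 1.95-fold and 1.78-fold, and Lgals3 was 1.41-fold lower. Epcam, a cell adhesion protein, was 16.3-fold lower and Camp, an antimicrobial peptide, 9.84-fold lower. The alveolar macrophage identity list had a median of 0.09: Chil3, a chitinase-like protein, stood at 0.65, Ear2, a ribonuclease, at 0.15, Car4, a carbonic anhydrase, at 1.22, and Krt79, a keratin, at -1.58. In interstitial macrophage-like cells the same list rose beside the profibrotic genes, by 1.63 [1.29 to 1.93] with 11 of 14 higher.

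The 7 genes of MHC class II, which present peptides to helper T cells, had medians of -1.20 in all macrophage clusters together, -0.87 in alveolar and -1.90 in interstitial macrophage-like cells, with 7 of 7 members lower in each. Cd74, the chain that guides MHC class II through the cell, was 1.92-fold lower in alveolar and 4.12-fold lower in interstitial macrophage-like cells, H2-Aa, which forms part of the peptide groove, 1.83-fold and 3.73-fold lower, and Ciita, the master switch of the family, 2.43-fold and 4.61-fold lower. Within the alveolar class the fall was -1.90 in the cluster that held most PBS cells and -0.04 in the cluster that held most bleomycin cells. Inside the Pf4-led and C1qa-led interstitial sub-clusters it was -0.16 and -0.54. In monocyte-like cells the direction was opposite, at 0.48, with H2-Aa 2.19-fold higher and its partner H2-Ab1 2.16-fold higher, and 1000 UMIs per cell gave 0.95. Finer clustering divided these cells into a cluster led by Plac8 and F13a1, with 41.0% of them in PBS, 60.2% in bleomycin and 70.3% in the treated library, and another led by Adgre4, and the MHC class II medians inside them were 0.42 and 0.27.

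The complement C1q and tissue macrophage list, markers of long-resident interstitial macrophages, had a median of -1.81 in interstitial macrophage-like cells with 11 of 11 members lower, and -2.85 with a limit of 10% mitochondrial UMIs. C1qa and C1qb, recognition chains of complement, were 3.44-fold and 3.04-fold lower, Pf4, a heparin-binding chemokine, 16.5-fold, Folr2, a folate receptor, 11.2-fold, and Lyve1, a hyaluronan receptor, 10.1-fold. Cd209f, a sugar-binding lectin, was 98.4-fold lower [63.5 to 172] and Cxcl13, which attracts B cells, 73.5-fold lower [49.6 to 119]. The monocyte-attracting chemokine list fell with it, at -2.32 (-3.17 to -1.54 over the settings), led by Ccl12 and Ccl8, ligands of the receptors that call monocytes into tissue, 24.2-fold and 12.1-fold lower. Ccl2, of the same family, was 6.35-fold lower. These class-wide falls also hold a change in the make-up of the class. Pf4, Folr2, Cd209f, Cxcl13, Ccl8 and Ccl12 were among the leading genes of the Pf4-led sub-cluster, with 128 cells in PBS and 35 in bleomycin. Inside that sub-cluster the C1q list was at -0.16 [-0.46 to 0.03], and inside the C1qa-led one at -0.67 [-0.80 to -0.43]. In alveolar macrophage-like cells the C1q list stood at 0.44, a value that ran from -1.40 to 1.98 over the settings and so gives no direction. The chemokine list there was at 0.23 (up to 2.03), with Ccl6, a chemokine of lung macrophages, 2.46-fold higher. Over all macrophage clusters the C1q list was at -1.57 and the chemokine list at -1.21.

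Transcripts of dividing cells made up a smaller part of macrophage RNA in bleomycin than in PBS. The cluster of dividing macrophages held 63 cells in PBS and 170 in bleomycin, which were 5.38% and 3.71% of all macrophage-like cells. The 16 genes of the proliferation list had a median of -1.12 in all macrophage clusters together, with 15 of 16 lower: Stmn1, which loosens microtubules, was 3.86-fold lower, Mki67, a coat of dividing chromosomes, 3.22-fold, and Top2a, which untangles DNA, 2.12-fold. NF-kB inflammatory genes had medians of -0.48 in alveolar and -0.49 in interstitial macrophage-like cells (-1.57 with doublets kept), with Cxcl2, which attracts neutrophils, 5.20-fold lower in the alveolar class, Tnf, an alarm cytokine, 1.55-fold lower, and Il1b, a fever-inducing cytokine, 2.36-fold higher. Type I interferon genes differed between the classes: the median was 0.82 in alveolar macrophage-like cells, where Ifi27l2a, an interferon-induced mitochondrial protein, was 2.41-fold higher, although settings placed it between 0.13 and 1.30, and -1.09 in interstitial macrophage-like cells (-0.55 with rare members counted), where Ifitm3, which blocks virus entry, was 7.27-fold lower. p53 target and hypoxia genes were higher in interstitial macrophage-like cells, at 1.14 and 0.88 (down to 0.75 and up to 1.41 in other settings), with Cdkn1a, a brake on the cell cycle, 2.32-fold and Ldha, which makes lactate, 2.26-fold higher.

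Cd47 (chromosome 16, 49800533 to 49915010, ENSMUSG00000055447) encodes the surface signal that tells phagocytes not to engulf a cell, and Sirpa its receptor. Cd47 was 1.19-fold higher in bleomycin alveolar macrophage-like cells and 1.44-fold higher in interstitial ones. Sirpa was 1.23-fold lower in the alveolar class and 1.42-fold higher in the interstitial class. The engulfment list that holds both genes had medians of 0.22 and 0.71. Stab1, a receptor for dying cells, and Timd4, another, went down 9.33-fold and 10.7-fold in interstitial macrophage-like cells while Mfge8 went up.

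**Figure D3:**
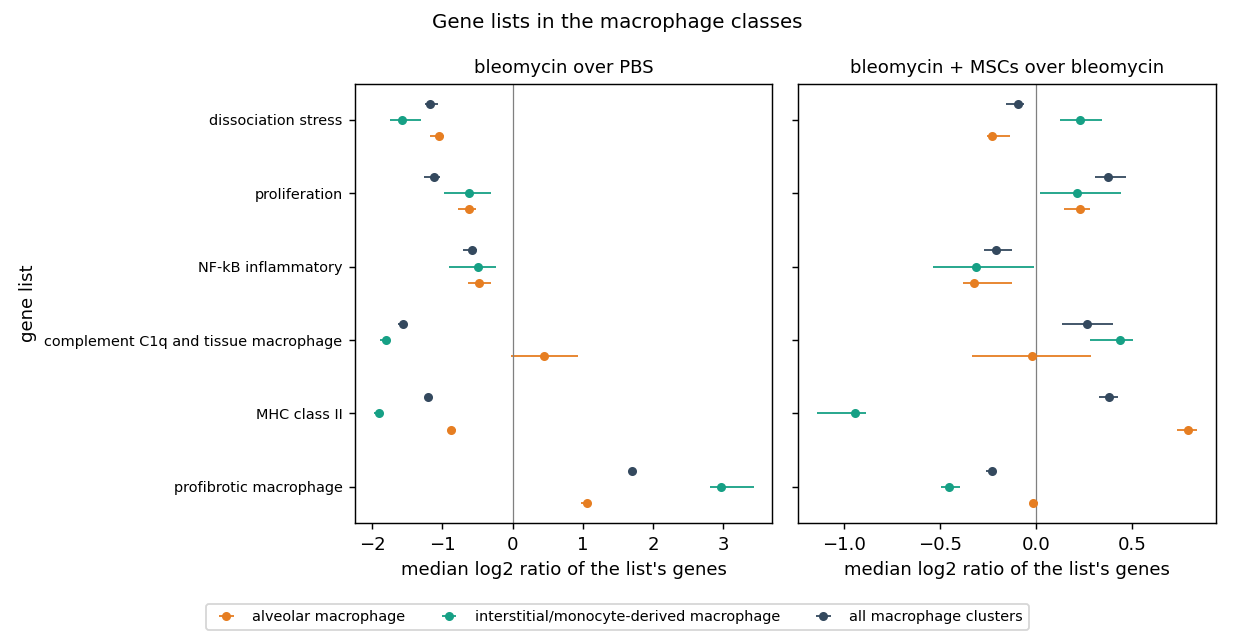
Median log2 ratio (horizontal axis) of the members of 6 gene lists (vertical axis) in alveolar macrophage-like cells, interstitial or monocyte-derived macrophage-like cells and all macrophage clusters, for bleomycin over PBS (left) and MSC-treated over bleomycin (right), with intervals for counting error. Profibrotic genes lie to the right and MHC class II genes to the left of 0 in the left panel, and MHC class II genes of the alveolar class lie to the right of 0 in the right panel.

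The few fibroblast-like cells recovered from bleomycin lungs carried a larger share of transcripts for matrix and inflammatory proteins. Whether their low number reflects the lung or the release of cells in the preparation was not tested. Genes of alveolar and contractile fibroblasts were scarcer in them. The list of fibrillar collagen and matrix genes had a median of 1.13 [0.99 to 1.46], 18 of 21 members higher, and settings placed it between 0.59 and 1.13. Col1a1 (chromosome 11, 94936224 to 94953042, ENSMUSG00000001506), a chain of the main scar collagen, was 3.97-fold higher [3.67 to 4.29], Col3a1, a collagen of pliable tissue, 4.93-fold, Fbn1, a microfibril protein, 5.06-fold, Eln, the elastic fibre protein, 3.97-fold, Fn1, a scaffold for cells, 2.67-fold, and Sparc, a collagen-binding protein, 1.45-fold. Postn, a matrix protein of injured tissue, was 6.76-fold higher [2.73 to 13.9] from 9 counts. Inflammatory fibroblast genes had a median of 1.75, or 0.83 in the other matrix of each sample, with C3, the central complement protein, 4.23-fold, Saa3, an acute-phase protein, 9.90-fold and Serpina3n, a protease inhibitor, 3.24-fold higher, while Cxcl14, a chemokine, was 4.75-fold lower. Cyp1b1, which metabolizes steroids and retinoids, was 10.8-fold higher [6.95 to 16.4] and Ebf2, a transcription factor, 8.77-fold [6.32 to 11.9].

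Contractile genes had a median of -1.32 in fibroblast-like cells (-1.01 with the undetected member at its bound) and alveolar fibroblast genes -1.27 (-1.12 likewise). Acta2 (chromosome 19, 34241090 to 34255590, ENSMUSG00000035783), the smooth-muscle actin of myofibroblasts, was 2.92-fold lower, from 505 to 7 counts, and Tagln, an actin-binding protein, 15.2-fold lower [4.06 to 899] with 1 count left. Npnt, a basement membrane ligand, was 28.2-fold lower [9.74 to 291] with 2 counts, Tcf21, a lung fibroblast transcription factor, 5.00-fold, Limch1, a regulator of contraction, 3.77-fold, and Inmt, a methyltransferase, 2.42-fold, whereas Gpc3, a growth factor co-receptor, was 3.40-fold higher. Itga8, an integrin chain of alveolar and contractile fibroblasts, fell from 1292 counts to none, at least 18.6-fold lower, and Epas1, a sensor of low oxygen, was 40.8-fold lower [14.1 to 421] with 2 counts. With finer clustering the alveolar fibroblast list turned to 0.53 and the contractile list to -0.12, so both losses depended on which cells were counted. TGF-beta target genes had a median of -0.07, with Tgfbi, a secreted adhesion protein, at -0.10 and Pmepa1, a brake on TGF-beta signalling, at 0.50. The chemokine list stood at 1.00 (up to 1.68 in other settings) and Csf1, which sustains macrophages, at 0.78 [-0.03 to 1.44].

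In the endothelial-like cells recovered from bleomycin lungs, both capillary gene lists were slightly lower than in PBS, over a class whose make-up of clusters also differed. The general capillary list had a median of -0.20, with Kit, a growth factor receptor, 2.43-fold and Sema3c, a guidance cue, 2.21-fold higher and Plvap, a pore diaphragm protein, 1.60-fold lower. The aerocyte capillary list, for the cells of gas exchange, was at -0.37 with 9 of 9 lower, led by Fibin, a secreted factor, 3.01-fold and Emp2, a membrane protein, 2.38-fold lower. The cluster led by Ednrb and Fibin went from 32.9% to 22.5% of the class, and inside it the aerocyte list stood at 0.11, against -0.71 in the main cluster. Car4, the carbonic anhydrase that releases carbon dioxide, was 1.30-fold lower. Activated and systemic-vein genes stood at 0.35 (0.82 with bounds), with Ntrk2, a neurotrophin receptor, 5.44-fold higher [4.28 to 6.79], Sparcl1, an adhesion-modulating protein, 1.74-fold higher and Vwf, which snares platelets, 1.49-fold lower. Ccdc152, a coiled-coil protein of unsettled function, was 8.91-fold higher. Fabp4, a fatty acid carrier, was 17.2-fold lower [6.83 to 97.2] and Slc6a2, the noradrenaline transporter, 10.7-fold lower [4.26 to 60.8], each with 3 counts left, and a cluster led by Slc6a2 held 74 cells in PBS and 1 in bleomycin. TGF-beta targets were at 0.01.

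T-like cells of bleomycin lungs carried more transcripts of regulatory genes, over a class whose make-up of clusters also differed. The regulatory T list had a median of 1.09, or 0.63 in the other matrix of each sample, and of 0.20 to 0.38 inside the 3 T-like clusters. Across the class Foxp3, the factor that defines regulatory T cells, was 4.29-fold [2.48 to 7.73], Tnfrsf4, a costimulatory receptor, 4.71-fold, Ikzf2, a zinc-finger factor, 2.26-fold and Ctla4, an inhibitory receptor, 2.13-fold higher. The effector and exhaustion list was at -0.53, with Ifng, the macrophage-activating interferon, 3.80-fold, Gzmb, a killing enzyme, 2.68-fold and Ccl5, a T cell chemokine, 1.45-fold lower, and Pdcd1, an inhibitory receptor, 2.46-fold higher, although the median turned to 0.31 once rare members were counted and ran from -0.76 to 0.09 inside the clusters. Olfr60, an olfactory receptor gene, was 9.68-fold and Cpd, a carboxypeptidase, 5.999-fold higher. Fosb, a partner of Jun, was 8.37-fold lower.

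In monocyte-like cells Ccl5 was 4.73-fold higher [3.13 to 7.15] and Abhd2, a lipase, 4.13-fold [3.12 to 5.45]. Cxcl2 and Nr4a2, an early-response nuclear receptor, were 25.7-fold lower [6.81 to 1529] and 25.3-fold lower [6.69 to 1502], each with 1 count left. The NF-kB list was at -0.50 in these cells (-0.29 and -0.23 inside their finer clusters) and at -1.41 in neutrophil-like cells, with Nlrp3, an inflammasome sensor, 3.06-fold, Cxcl2 2.78-fold and Nfkbia, which restrains NF-kB, 2.66-fold lower in neutrophils; with at least 1000 UMIs per cell the neutrophil median turned to 0.13. Interferon genes were at -0.61 in T-like (-0.93 to -0.21 over the settings), -0.41 in monocyte-like (-0.52 to -0.11) and 0.44 in conventional dendritic-like cells, the last turning to -0.07 at 1000 UMIs per cell. Proliferation was at 0.50 in B-like cells and at -0.61 in T-like cells, the latter turning to 0.63 with at least 1000 UMIs per cell, and in endothelial-like cells its -1.05 became 0.34 with undetected members at their bounds. Transcripts carried over from other cells, such as haemoglobin and surfactant, were lower in bleomycin in most classes, at -1.42 in alveolar macrophage-like and -5.14 (-4.33 with bounds) in conventional dendritic-like cells. They stood at -0.09 in B-like and -0.29 in NK-like cells, and in the latter Scgb1a1, the secretory protein of airway club cells, was 1.81-fold and Igkc, an antibody light chain, 5.41-fold higher.

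The suspension from lungs of mice given bleomycin and MSCs had about the same large share of macrophages as that from bleomycin lungs and a still smaller share of vessel cells. All macrophage clusters together made up 49.2% of cells, 0.982 times the bleomycin share [0.942 to 1.02]. Within them the balance moved: the mixed cluster led by Mfge8 and Mmp12 shrank, and neutrophil-like and monocyte-like cells took a larger part of the suspension. The mixed cluster went from 12.5% to 8.93% [0.652 to 0.785 times]. Alveolar macrophage-like cells were at 33.0% and 35.2%, a ratio of 1.07 [1.01 to 1.12] that turned to between 0.980 and 0.994 in 3 other settings, and interstitial macrophage-like cells at 4.56% and 5.02% [0.961 to 1.26 times], a ratio that ran from 0.938 to 1.43 over the settings. Neutrophil-like cells, early responders to damage, went from 6.33% to 10.1% [1.43 to 1.77 times, and 2.97 times with at least 1000 UMIs per cell], monocyte-like cells, which feed the macrophage pool, from 3.84% to 5.77% [1.31 to 1.73], and NK-like cells from 2.10% to 2.95% [1.16 to 1.71]. T-like cells went from 12.7% to 10.6% [0.764 to 0.910], conventional dendritic-like cells from 3.05% to 2.44% [0.666 to 0.961], and B-like cells were at 13.8% and 14.5%.

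Blood endothelial-like cells fell from 3.84% (351 cells) to 0.372% (32 cells), a share 0.0983 times as large [0.0653 to 0.139], or 0.150 with each library clustered alone. Fibroblast-like cells fell from 59 to 18 cells [0.180 to 0.558 times], mural-like cells from 5 to 0, and lymphatic endothelial-like cells from 8 to 1. A count of 0 in 8603 cells leaves room for a mural-like share of up to 0.0429%. These classes had too few cells in the treated library for their genes to be compared with bleomycin. The sparse droplets of mixed endothelial and fibroblast genes held 0.151% of cells, the cluster led by Cxcl2, Acod1 and Ccl3 0.965%, the cluster of surfactant and airway genes 0.325%, the satellite-repeat cluster 0.0581%, and the pair of mixed-cell clusters 0.0349% and 0.116%. Plasmacytoid dendritic-like cells were at 0.593%, ciliated-like cells at 1.10% against 0.732% [1.09 to 2.09 times], mesothelial-like cells at 31 against 32 cells, basophil or mast-like cells at 14 against 4, and erythroid-like cells at 5 against 2. B-like cells in the treated library lay in the sparse cluster for 78.2% and neutrophil-like cells for 95.3%.

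In macrophages of MSC-treated lungs the antigen-presenting genes were higher than in bleomycin in alveolar cells and lower in interstitial ones. Spp1 itself was lower, but most of its companions changed little in alveolar macrophage-like cells. The interstitial class as a whole held more transcripts of some genes of resident macrophages. MHC class II genes had a median log2 ratio of 0.79 in alveolar macrophage-like cells [0.73 to 0.84], with 7 of 7 higher, -0.94 in interstitial macrophage-like cells [-1.14 to -0.88], with 7 of 7 lower, and 0.38 in all macrophage clusters together. Cd74 was 1.79-fold, H2-Aa 1.91-fold and H2-Eb1, another chain of the peptide groove, 1.86-fold higher in the alveolar class, while in the interstitial class H2-Ab1 was 2.37-fold, H2-Aa 2.19-fold and Cd74 1.92-fold lower. The alveolar rise was found inside 4 of its clusters, at 1.19, 0.60, 0.95 and 0.24, and the interstitial fall narrowed to -0.42 with a limit of 10% mitochondrial UMIs. The cluster at 0.60 held most bleomycin cells of the alveolar class, and there the list had not clearly fallen from PBS to bleomycin (-0.04 [-0.19 to 0.13]). In PBS, bleomycin and the treated library, H2-Aa stood there at 395, 425 and 698 CPM, and Cd74 at 1590, 1332 and 2057.

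Spp1 was 1.70-fold lower in alveolar macrophage-like cells, 1.48-fold lower in interstitial macrophage-like cells and 1.72-fold lower in all macrophages. Inside the cluster that held most alveolar macrophage-like cells of PBS it was higher, at 1315 CPM against 1122 in bleomycin, and in the other macrophage clusters it was lower. The share of cells with Spp1 moved less. With cells thinned to 1000 UMIs it was 70.6% in alveolar, 57.4% in interstitial and 71.9% in all macrophage-like cells, against 71.6%, 67.3% and 76.7% in bleomycin, and unthinned it was 93.3%, 73.1% and 91.6%. T-like and B-like cells, the background, showed it in 3.94% and 4.12% thinned, 5.04% and 4.34% unthinned, at median depths of 1529.5 and 1033 UMIs, and 32 alveolar, 7 interstitial and 41 of all macrophage-like cells were left out. The profibrotic list had medians of -0.01 in alveolar macrophage-like cells, -0.45 in interstitial ones [-0.49 to -0.39], with 14 of 15 lower, and -0.23 in all macrophages; settings placed the interstitial value between -0.53 and -0.22. Alveolar identity genes fell beside it in the interstitial class, by -0.38 [-0.57 to -0.31] with 12 of 14 lower. Arg1 was 2.48-fold and 2.52-fold lower in the alveolar and interstitial classes, and Apoe was 1.85-fold lower in the alveolar class. In the interstitial class Mmp12 was 1.85-fold, Gpnmb 1.82-fold, Mfge8 1.67-fold and Fabp5 1.52-fold lower, while Cd9 and Ctsd stood at 0.08 and -0.20.

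Interstitial macrophage-like cells of treated lungs had a C1q and tissue macrophage median of 0.44, with 10 of 11 higher, a value that ran from 0.04 to 0.67 over the settings. With finer clustering it was 0.21 in the C1qa-led sub-cluster and -0.19 [-0.29 to 0.04] in the small Pf4-led one, so the rise was not found in both. Lyve1 was 7.15-fold higher [5.14 to 10.4] and Folr2 2.18-fold, with C1qa 1.37-fold and Pf4 at 0.01. Cxcl13 was 14.9-fold higher [9.97 to 24.3], Marco (chromosome 1, 120474538 to 120505024, ENSMUSG00000026390), a scavenger receptor for particles and bacteria, 11.4-fold [7.70 to 18.2] and Timd4 11.3-fold [6.39 to 24.2]. With the treated library clustered alone, Cxcl13, Lyve1, Folr2 and Timd4 were among the leading genes of a cluster of 40 cells. How far their rises rest on those few cells was not tested. AW112010, a long noncoding RNA of activated immune cells, was 3.54-fold lower. Scgb1a1, a transcript of airway club cells that other cells carry as free RNA, was 3.99-fold lower, at 99.7 CPM, while it made up 0.849% of the free RNA in bleomycin and 1.40% in treated lungs. Ccl8 and Ccl12 went down further, 2.94-fold and 2.99-fold, with the chemokine list at -0.22 (-1.09 to -0.12 over the settings). Engulfment genes had medians of 0.11 in the interstitial and 0.06 in the alveolar class. Cd47 was at 0.06 in alveolar and 0.08 in interstitial macrophage-like cells, and Sirpa at 0.02 and -0.00.

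Alveolar macrophage-like cells went the other way in Marco, which was 3.48-fold lower [3.22 to 3.76], and in Egfem1, a gene with growth-factor-like domains, 2.64-fold lower. Pmepa1 was 2.06-fold higher [1.94 to 2.18]. The alveolar identity list was at -0.18, with Pparg, the master regulator of these cells, 1.67-fold and Chil3 1.33-fold lower and Fabp4 1.45-fold higher. Inflammatory NF-kB genes were lower, at -0.32 in alveolar and -0.31 in interstitial macrophage-like cells, with Tnf 2.21-fold and Cxcl2 1.49-fold lower in the alveolar class and Il1b at -0.01. Proliferation genes were higher, at 0.38 in all macrophages with 16 of 16 higher: Stmn1 rose 1.40-fold, Top2a 1.37-fold and Mki67 1.12-fold. Interferon genes were at 0.17 in the alveolar class (-0.14 in the other matrix of each sample) and -0.08 in the interstitial class. The p53 list was at 0.14 and -0.01, hypoxia genes at 0.05 and -0.14, and the chemokine list at 0.13 in the alveolar class.

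Outside the macrophages most of the list medians given here differed modestly between the treated library and bleomycin, while some single genes differed several-fold. Monocyte-like cells had an MHC class II median of -0.03, a profibrotic median of 0.10 and an interferon median of 0.25 with 13 of 14 higher, while inside their Plac8-led and Adgre4-led clusters the values were -0.14 and 0.09, -0.27 and -0.06, and 0.15 and 0.17. Rbks, a ribose kinase, was 2.48-fold and Pde4b, which breaks down cyclic AMP, 2.07-fold higher there, and Hpgd, which inactivates prostaglandins, 2.10-fold and Dynll1, a motor protein light chain, 2.02-fold lower. Neutrophil-like cells had an NF-kB median of 0.30, with Ccl3, a chemokine, 3.83-fold higher, that turned to -0.11 with at least 1000 UMIs per cell. In T-like cells Olfr60 was 5.44-fold and Rgs1, a brake on chemokine receptors, 2.72-fold lower, the regulatory list was at -0.12 with Tnfrsf4 1.99-fold and Ikzf2 1.49-fold lower, and the effector list was at 0.23. The make-up of this class also differed, with the cluster led by Cxcr6 and Icos at 33.8% in bleomycin and 18.1% in the treated library. Inside the T-like clusters the regulatory medians ran from -0.001 to 0.34 and the effector medians from -0.08 to 0.54. Ly6d, a surface protein of early B cells, was 9.39-fold and Mef2c, a transcription factor, 6.80-fold higher in T-like cells. Both are made by B cells, and 7 of 7 B cell markers rose with them, by a median of 3.57-fold. Finer clustering set apart a cluster with markers of both T and B cells, with 4 cells in PBS, 15 in bleomycin and 48 in the treated library. Whether such cells account for the rise was not tested. Proliferation genes in conventional dendritic-like cells, at -1.26 (-0.67 with bounds), turned to between 0.13 and 0.35 in 3 other settings.

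Genes that differed at least 2-fold between bleomycin and PBS lay nearer to PBS in the treated library for more than 50% of them in every class measured except conventional dendritic-like cells. With a random part of the bleomycin cells used to pick the genes and the rest as reference, the share was 69.3% of 1368 genes in all macrophages, 67.7% of 539 in T-like, 65.2% of 1372 in interstitial macrophage-like, 60.6% of 429 in neutrophil-like and 60.3% of 416 in NK-like cells. It was 58.6% in monocyte-like, 57.8% in alveolar macrophage-like, 56.4% in B-like and 49.9% in conventional dendritic-like cells. Bleomycin cells drawn at random in place of the treated library gave 32.6% to 59.3% in all macrophages, 40.4% to 57.5% in T-like and 39.2% to 60.0% in interstitial macrophage-like cells, and these 3 lay above their range at 1.5-fold and 3-fold too. Such draws hold the sampling of cells from 1 bleomycin library and not the difference between preparations, so they do not show that the treatment moved these genes. Class-wide values also mix changes within cells with changes in the make-up of clusters. In PBS, bleomycin and the treated library, the cluster led by Cxcr6 and Icos held 16.4%, 33.8% and 18.1% of T-like cells. The mixed macrophage cluster held 0.427%, 24.9% and 18.1% of all macrophages. Alveolar macrophage-like cells (40.3% to 61.5% at 2-fold) and conventional dendritic-like cells (30.7% to 70.8%) lay inside their ranges at all thresholds, and in the remaining classes the outcome depended on the threshold. Neutrophil-like and NK-like cells lay above their ranges at 2-fold (41.7% to 56.6% and 46.9% to 57.9%) but inside them at 3-fold, with 58.8% (33.3% to 63.7%) and 53.1% (37.0% to 61.7%). Monocyte-like and B-like cells lay inside theirs at 2-fold but above them at 1.5-fold, with 58.4% (49.4% to 56.8%) and 59.0% (48.7% to 54.4%), and at 3-fold the B-like share turned to 48.8%. The treated library also lay between bleomycin and PBS in UMIs per cell in each of these classes except interstitial macrophage-like cells, where it was level with bleomycin. Its mitochondrial share of UMIs lay between them in each class except neutrophil-like cells. In PBS, bleomycin and the treated library that share was 2.56%, 1.80% and 2.39% in interstitial macrophage-like and 2.76%, 1.59% and 2.29% in T-like cells. Whether such differences between libraries account for the direction was not tested.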

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

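Of the tests in this part, those on PBS cells thinned to bleomycin depth, on macrophage expansion, on handling of the PBS preparation on RNA of other cells and on other macrophage clusters were chosen after the result was seen.

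Barcodes with 10 to 100 UMIs, which the comparisons leave out because they hold free RNA or remnants of cells, carried more macrophage marker RNA in both bleomycin libraries than in the PBS control. The 9 alveolar macrophage markers gave 0.917% of the UMIs in such barcodes in bleomycin and 0.656% in MSC-treated lungs, against 0.164% in PBS. The 11 markers of interstitial or monocyte-derived macrophages gave 0.128% and 0.109%, against 0.0483% in PBS. The macrophage shares among the kept cells were also above PBS in both libraries.

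Blood endothelial-like cells made up a much smaller share in bleomycin than in PBS lungs, and a smaller share still in MSC-treated lungs. The fixed UMI minimum does not account for it, since with PBS cells thinned to bleomycin depth the fold was 0.202 [0.179 to 0.226]. Endothelial cells broken in the loaded suspension would add their markers to the sparse barcodes. There the markers stood at 0.348 times the PBS share [0.321 to 0.376] in bleomycin and 0.125 times [0.108 to 0.144] in MSC-treated lungs. These falls argue against breakage as the whole cause. The markers fell less than the share of cells did, so breakage of some of the cells stays open. Growth of the macrophage pool alone is argued against by a fold of 0.410 [0.364 to 0.459] among cells outside the macrophage clusters. Loss of vessel cells during digestion and washing, before loading, stays open and was not tested, and so does a true loss of vessels.

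Dissociation stress genes were lower in both bleomycin libraries than in PBS in every class that could be compared. With each cell thinned to 1000 UMIs the median over 10 classes was -1.13 (from -1.48 to -0.65), against -1.05 before thinning. This does not decide on deeper sequencing of the PBS library. The list is taken as a share of the UMIs of a class, which random thinning leaves nearly unchanged. A difference in handling of the PBS preparation cannot be told apart from an effect of bleomycin, because each group is 1 preparation. The median was under 0 in 18 of 18 class comparisons, which restates the pattern and so counts neither for nor against handling. A biological cause was not tested.

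Interstitial or monocyte-derived macrophage-like cells of bleomycin lungs had higher profibrotic genes and lower C1q and MHC class II genes than those of PBS. RNA of other cells in the droplets is argued against, since the profibrotic median stayed at 2.96 [2.77 to 3.38] after ambient subtraction. Alveolar macrophage identity genes rose in the class too, by 1.63 [1.29 to 1.93], but cells or RNA of other macrophage clusters are argued against as the whole cause, since without the share of them that these genes call for (9.19% to 28.9%) the profibrotic median was 2.82 [2.70 to 3.45] or more. In the sub-cluster at finer resolution that held most PBS cells (128, against 35 of bleomycin), the medians of profibrotic, C1q and MHC class II genes were 0.39 [0.20 to 0.63], -0.16 [-0.46 to 0.03] and -0.16 [-0.37 to -0.04], far smaller than the 2.96, -1.81 and -1.90 of the whole class, and in the one with most bleomycin cells (320, against 10 of PBS) they were 1.32, -0.67 and -0.54. These values lean to a shift between subsets, which still cannot be told apart from a change within cells, because the profibrotic value stayed above 0, 35 and 10 cells are few, and sub-clusters drawn on expression would move a changed cell from one to the other; a biological cause was not tested.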

How the results depend on the processing

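Shares among immune cells, PBS thinned to bleomycin depth, the alveolar macrophage-like class with the mixed macrophage cluster, the blood endothelial-like class with the sparse mixed cluster, and all macrophage clusters as a unit were tests chosen after the data were seen.

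Ratios below are bleomycin over PBS (first comparison) or MSC-treated over bleomycin (second comparison). Shares are folds and list medians are log2. Of the class shares under an alternative, 125 stayed within their counting interval, 53 moved beyond it and 3 reversed a direction that the interval had set. For list medians the numbers were 1489, 366 and 15, for named genes 130, 26 and 0, and for the share of genes nearer to PBS 12, 5 and 1. Ambient subtraction left 179 list medians and 36 named genes in place and reversed none. The direction of the macrophage and endothelial shares and of the macrophage profibrotic and MHC class II medians held throughout, except for the interstitial share in the second comparison, whose interval included 1, the alveolar share there, and the profibrotic alveolar median there, which lay near 0. Named genes were recomputed in the other matrix, with ambient subtraction, with median-of-ratios scaling and with thinning to 1000 UMIs. For each value below, the cause was not tested.

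With a minimum of 1000 UMIs, the share of all macrophages was 5.25 in the first and 0.932 in the second comparison, and in the first that of alveolar macrophage-like cells 2.84 and of blood endothelial-like cells 0.180. The fibroblast matrix median was 0.66. MHC class II was at -0.70 and 0.90 in alveolar and -2.42 and -0.80 in interstitial macrophage-like cells for the first and second comparison, and at -1.12 in all macrophages for the first. The profibrotic list was at 0.75 and 0.0229 in the alveolar class, and at -0.27 in the interstitial class for the second. Neutrophil NF-kB reversed to 0.13 and -0.11, and conventional dendritic proliferation in the second comparison to 0.13.

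With PBS thinned to bleomycin depth, first-comparison shares were 4.23 for all macrophages, 3.12 for alveolar macrophage-like and 0.202 for blood endothelial-like cells. Among immune cells all macrophages stood at 3.01 and alveolar macrophage-like cells at 2.29. With each library clustered alone, the alveolar share was 3.22 and the endothelial share 0.265 in the first comparison and 0.150 in the second. With the sparse cluster of mixed endothelial and fibroblast genes counted as blood endothelial-like, their share was 0.137 in the first comparison.

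In the other matrix of each sample, the first comparison gave an alveolar share of 3.01, a matrix median of 0.75, MHC class II of -0.62 in alveolar, -1.85 in interstitial and -1.17 in all macrophages, and a profibrotic median of 0.94 in alveolar and 1.62 in all macrophages. In the second comparison the interstitial profibrotic median was -0.26, and alveolar interferon reversed to -0.14.

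With a limit of 10% mitochondrial UMIs, the alveolar share was 4.24 in the first comparison and reversed to 0.980 in the second. MHC class II was at -2.59 and -0.42 in the interstitial class, and at -1.11 in all macrophages for the first. The profibrotic list was at 1.65 and -0.0750 in the alveolar and 3.50 and -0.25 in the interstitial class. Dendritic proliferation reversed to 0.22 in the second.

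With doublets kept, the alveolar share was 4.27 and reversed to 0.994, and the matrix median was 0.62. MHC class II was at -2.48 and -0.53 in the interstitial class, and at -1.09 in all macrophages for the first comparison. The profibrotic list was at 1.68 and -0.0766 in the alveolar and 3.55 and -0.27 in the interstitial class. Dendritic proliferation reversed to 0.35 in the second.

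At resolution 0.5 the alveolar share was 4.51 and reversed to 0.990. MHC class II was at 0.67 in the alveolar class for the second comparison and at -2.65 and -0.66 in the interstitial class. The profibrotic list was at 1.75 and -0.0737 in the alveolar and 3.50 and -0.22 in the interstitial class. At resolution 2.0 the first comparison gave a matrix median of 0.59, MHC class II of -1.74 in interstitial and -1.11 in all macrophages, and the alveolar fibroblast list reversed to 0.53.

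With median-of-ratios scaling, the matrix median was 0.80 and MHC class II was at -1.76 in the interstitial class for the first comparison and at -1.06 and 0.31 in all macrophages. The profibrotic list was at 1.12 and -0.0494 in the alveolar class, -0.53 in the interstitial class for the second, and 1.84 and -0.30 in all macrophages, where the p53 list reversed to 0.0384 and -0.000539.

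With each cell thinned to 1000 UMIs, MHC class II was at -0.75 and 0.86 in alveolar, -1.75 in interstitial for the first comparison, and -1.34 and 0.29 in all macrophages. The profibrotic list was at -0.0286 in the alveolar and -0.33 in the interstitial class for the second, and at 1.83 and -0.14 in all macrophages. Values that reversed lay near 0: interstitial engulfment at -0.0530 and the stress list of all macrophages at 0.00875 in the second comparison, and the p53 list of all macrophages at 0.00535 and alveolar hypoxia at 0.00967 in the first.

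With the mixed cluster counted in the alveolar class, MHC class II was at -0.95 and 0.70 and the profibrotic list at 2.15 and -0.17. With no minimum above 1 UMI, endothelial proliferation reversed to 0.19 and the T effector list to 0.31, both in the first comparison. At a threshold of 3-fold the B-like share of genes nearer to PBS reversed to 48.8%.

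Depth limits the classes with few cells. Fibroblast-like cells numbered 59 in bleomycin, and on simulated data a 2-fold change there was placed on the right side for 58% of changed genes. Mural-like cells in both bleomycin libraries, and endothelial-like and fibroblast-like cells in the treated library, were too few to compare.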

Other observations

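No test in this part was chosen after the result was seen, since the values below were not tested.

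In barcodes with 10 to 100 UMIs the markers of secretory airway cells gave 0.461% of UMIs in PBS, 0.940% in bleomycin and 1.43% in MSC-treated lungs, with Scgb1a1 alone at 0.414%, 0.849% and 1.40%. Erythroid markers gave 1.38%, 0.0325% and 0.111%. Blood endothelial markers gave 0.256%, 0.0889% and 0.0320%, and fibroblast markers 0.0920%, 0.0254% and 0.0144%.

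Set against PBS directly, MSC-treated lungs had MHC class II medians of -0.11 in alveolar macrophage-like, -2.98 in interstitial macrophage-like and 0.88 in monocyte-like cells. Profibrotic medians were 1.18, 2.52 and, over all macrophage clusters, 1.58.

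Spp1 levels in single macrophage clusters ran in the order PBS, bleomycin and MSC-treated at 229, 1122 and 1315 CPM in the cluster that held most alveolar macrophage-like cells of PBS, and at 398, 8755 and 4380 in the cluster that held most of them in bleomycin. In the mixed cluster, with too few cells in PBS, the levels were 14372 in bleomycin and 9875 in MSC-treated lungs. The cluster of dividing macrophages, with Top2a and Mki67, stood at 266, 5580 and 3112.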
